A study of Homo sapiens with 14 samples.

How the data were processed

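Single-cell RNA libraries (10x Chromium version 3 chemistry) were made from 12 skin biopsies and from 2 preparations called native fibroblasts. Per the labels, the skin was dissociated with a whole-skin kit, and live single cells were sorted as propidium iodide negative and DyeCycle Violet positive. The deposited matrices hold raw UMI counts (unique molecular identifiers, the number of distinct captured transcripts) per gene and barcode. They were taken as already restricted to cell-containing barcodes, since the lists hold only 3825 to 11668 barcodes per biopsy. Per the file headers, the authors made the matrices with Cell Ranger 5.0.0 for replicate 1, 6.0.1 for replicates 2 and 4, and 6.0.0 for replicate 3 and the native libraries. The deposited processing notes name Cell Ranger 3.0.1, Seurat and genome build hg38 instead. All 14 matrices list the same features. The gene annotation release is not stated, so no chromosome positions are given and genes carry the symbols and identifiers of the feature lists.

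Each of the 4 replicates was 1 donor, biopsied once at 3 sites: a vehicle site injected with medium, a scalp site injected with the donor's own scalp fibroblasts and a sole site injected with the donor's own sole fibroblasts. The time since injection was 2 weeks for replicate 1, 2 months for replicate 2, 5 months for replicate 3 and 17 months for replicate 4, so time and donor cannot be separated. The Cell Ranger release also followed the donor, and the comparisons were made within donors. The pairing was checked on each library's deviation from its group mean. Libraries of the same donor correlated at 0.548 or more over keratinocyte sums in 12 of 12 pairs, and at 0.266 or more over fibroblast sums in 9 of 9 pairs. None of the 66 pairs of libraries held the same counts.

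Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial counts were kept. Scrublet scores in scanpy 1.11.5 ranked them, and the highest-scoring barcodes were removed as predicted doublets at a fixed rate of 0.8% per 1000 barcodes. Of 85279 barcodes from the biopsies, 76674 passed, 5013 were removed as predicted doublets (3.06% to 9.33% per library), and 71661 were used. The biopsy libraries held 28303040 to 109334376 UMIs each. Clustering used the 2000 most variable genes, 40 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1). No batch correction was applied. A cluster received a cell class when its 50 leading genes, each detected in at least 25% of its cells, held at least 3 markers of the class. It stayed unnamed if most of its cells were predicted doublets or if another class had more markers among its 10 leading genes. So did clusters with low UMI counts and no marker of the class among those 10. Classes are therefore written with "-like". The classes covered 70009 cells, and 1652 cells of other clusters stayed unnamed and were left out of the class comparisons. Among these clusters was cluster 19 (1342 cells before doublets were removed), whose leading genes were those of cycling cells such as TOP2A and MKI67.

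Counts were summed per library and class wherever a library had at least 20 cells of the class. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test; R 4.3.3) with donor as a block and treatment as the factor. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. In keratinocyte-like cells 15634 genes were tested over 12 libraries. In fibroblast-like cells 18870 genes were tested over 10 libraries, because the vehicle and scalp sites of replicate 3 had 19 and 16 such cells. Fibroblast means therefore cover replicates 1, 2 and 4. Gene lists were tested with limma 3.58.1 camera (voom weights, preset inter-gene correlation 0.01) and with limma fry. Adjusted values cover the lists tested in that comparison, 35 in keratinocyte-like and 36 in fibroblast-like cells. Levels are CPM (a gene's count as a share of the total of the class sum, scaled by 1e6), given as mean and SD over donors.

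The comparisons, the 36 gene lists, the class markers and the rule for naming genes were chosen before the data were examined. The rule names up to 10 genes each way past the threshold with at least 10 CPM and the same sign in every donor, ranked by size. It fills each direction up to 10 with the smallest p values, and adds a fixed set of epidermal, HOX, Wnt and matrix genes and up to 4 members of each list described. For the native pair it names the 15 largest ratios each way at 50 CPM or more and the fixed set. Genes named outside this rule are marked where they appear.

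Class shares were compared with exact two-sided sign-flip permutation tests of the 4 donor differences, whose smallest possible p is 0.125, adjusted over 33 tests. The share of cells with a KRT9 UMI was taken after thinning each cell to 2000 UMIs, and cells below that depth were left out. Shares carry exact Clopper-Pearson intervals at 95%, which, like the limits from counts of 0, cover counting error only. Where 0 cells had a UMI the limit given is 3 counts over the number of cells, which is lower than the upper end of the exact interval. The native libraries have no replicate, so their genes carry exact Poisson intervals and no p value. Their ratios were taken after adding 1 CPM, and the median ratio of a list was placed among 10000 random lists of the same size. The 100 genes with the largest ratio each way formed lists that were tested in the fibroblast-like cells of the biopsies.

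The test was tested on simulated data drawn from the real means, library sizes and dispersions, with changes added at the sole sites. Changes were placed only in genes averaging at least 10 CPM. Genes were drawn independently, and each donor had the same mean at all sites before changes were added. The recovery therefore does not cover genes at lower levels, such as KRT9, or genes that vary together. In keratinocyte-like cells, 98 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, with 22 false calls among 15419 genes. In fibroblast-like cells the counts were 98 of 100, 100 of 100 and 16 false calls among 18436 genes. In both classes the false calls were a larger share of all calls than the threshold of 0.05. DESeq2 1.42.0, edgeR without the filter on low counts, without the donor block, with RLE size factors or with only the groups compared, sums thinned to the lowest total, other cell filters, other clustering resolutions, doublets kept and each replicate left out were tried as alternatives. Genes of the Y chromosome, XIST and TSIX were left out before counts were summed, for the donors' privacy. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9 were used.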

Results

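Transcripts of single cells were counted in 14 libraries. The 12 biopsy libraries came from 4 donors, each with a vehicle site, a scalp site and a sole site in skin outside the palms and soles. The vehicle site had received medium, and the other sites the donor's own fibroblasts from the scalp or the sole. The 2 further libraries held native scalp and native sole fibroblasts, 1 library each. The comparisons ask whether fibroblasts of volar skin (palm and sole) change the identity of the skin they are placed in. Total counts per library were 66873738, 57206567 and 64663006 UMIs for the vehicle, scalp and sole sites of replicate 1 (2 weeks after injection). They were 86358832, 85906367 and 97241595 for replicate 2 (2 months), 28303040, 30963933 and 31339747 for replicate 3 (5 months), and 86741885, 109334376 and 101795424 for replicate 4 (17 months). The native scalp library held 156118146 UMIs and the native sole library 179076174. After filtering, the biopsies gave 3356 to 9792 cells each with a median of 6112 to 16029 UMIs per cell, and the native libraries 4214 (scalp) and 9981 (sole) cells.

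The native fibroblast libraries compare sole and scalp fibroblasts outside the injected sites. The labels do not say whether these cells were fresh or cultured, so they may differ from the cells injected. Native sole fibroblasts carried the positional code of the distal limb, which native scalp fibroblasts lacked. All 8 measured distal HOX genes were at least 2-fold higher in the sole library, with a median log2 ratio of 4.41, above every one of 10000 random lists (percentile 100). HOXA13 (ENSG00000106031), the HOX gene of hands and feet, was at 35.8 CPM in sole cells (95% interval 34.9 to 36.8) and at 0.0806 CPM in scalp cells (0.0416 to 0.141). HOXC10 was at 44.5 CPM in the sole library and had 0 counts in the scalp library, and HOXA10 was at 50.6 against 0.604 CPM. Of the 15 measured anterior and central HOX genes, 10 were at least 2-fold higher in scalp cells and 4 in sole cells (median log2 ratio -2.26). HOXD10 and HOXD13 had 3 counts or fewer in each library.

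The native sole library was also rich in Wnt inhibitors and in KRT19, a keratin of simple epithelia. KRT19 was at 431 CPM (428 to 434) in sole cells and at 1.63 CPM (1.43 to 1.85) in scalp cells, a ratio of 164. Of 8 measured Wnt inhibitors, 5 were at least 2-fold higher in sole cells and 0 in scalp cells (median log2 ratio 1.82). DKK1 was at 391 against 55.2 CPM and DKK3 at 108 against 8.14 CPM, while DKK2 was at 36.5 against 53.3 CPM. The ligand gene WNT5A (207 against 13.1 CPM), the growth factor gene NRG1 (81.1 against 3.50 CPM), GRP (68.2 against 0.228 CPM) and IGFBP7 (192 against 8.59 CPM) were higher in the sole library too. Genes higher in the scalp library included GPC3 (52.0 against 0.127 CPM), the Wnt agonist RSPO3 (124 against 2.38 CPM), the transcription factor gene ZIC1 (79.4 against 1.37 CPM), the prostaglandin synthase gene PTGDS (557 against 30.4 CPM) and the growth factor gene FGF7 (107 against 12.7 CPM). Of 28 measured fibrillar and associated collagens, 7 were at least 2-fold higher in sole and 1 in scalp cells (median log2 ratio 0.57, percentile 100 of the random lists). COL1A1 was at 3372 CPM in sole and 2429.7 CPM in scalp cells, and COL3A1 at 481 and 514 CPM. In all, 36 genes were at least 4-fold higher in the sole and 45 in the scalp library among 3211 genes at 50 CPM or more. With 10 CPM added in place of 1 before taking ratios, these counts were 28 and 29. The labels give both libraries the same donor, and with 1 library each the spread between donors was not measured. KRT14 (2.34 CPM in scalp, 0.0191 in sole), PECAM1 (0.497 and 0.0572) and PTPRC (0.0201 and 0.350) were low in both libraries.

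**Figure D1:**
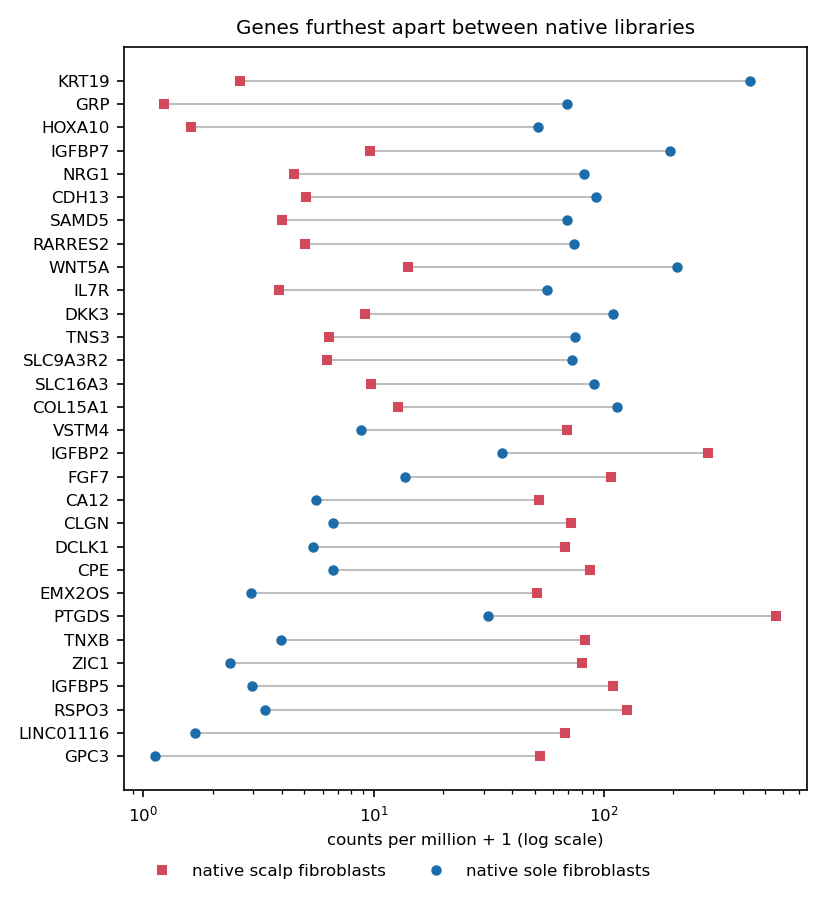
Level as CPM plus 1 (horizontal log axis) of the 15 genes with the largest ratio each way between the native sole and the native scalp fibroblast library. Squares are the scalp and circles the sole library, joined by a line per gene, with 1 library per group and no error bar for donors. KRT19 lies at 431 CPM in the sole and 1.63 CPM in the scalp library, and GPC3 at 0.127 and 52.0 CPM.

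The biopsies held keratinocyte-like, fibroblast-like, vascular and lymphatic endothelial-like, pericyte-like (named from pericyte and smooth muscle markers together), T and NK-like, myeloid-like, mast-like, B and plasma-like, melanocyte-like and appendage-like cells. Their shares are shares of a dissociated and sorted suspension, not of the tissue. They differed more between donors than between sites. In replicate 3, keratinocyte-like cells made up 95.2%, 95.3% and 92.7% of classified cells at the vehicle, scalp and sole site, and fibroblast-like cells 0.554%, 0.455% and 0.825%. In replicate 1 keratinocyte-like cells made up 46.5% at the vehicle site, 5.90% at the scalp site and 1.70% at the sole site, the last from 96 cells. Their share was lower at the sole than at the scalp site in 4 of 4 donors, by 3.26 points on average (27.5% ± 43.6 against 30.8% ± 43.1, SD, n = 4; difference SD 0.763; exact permutation p = 2/16 of the sign patterns, adjusted p = 0.688). Vascular endothelial-like cells took a higher share at the scalp than at the vehicle site in 4 of 4 donors (8.15% ± 4.72 against 4.73% ± 2.72, SD, n = 4; exact permutation p = 2/16, adjusted p = 0.688). Lymphatic endothelial-like cells were at 1.23% ± 0.916 at the sole and 0.601% ± 0.673 at the vehicle site, higher in 4 of 4 donors. Mast-like cells were at 5.51% ± 5.89 at the scalp and 4.33% ± 5.25 at the vehicle site, higher in 4 of 4, though in replicate 3 by 1 cell against 0 (SD, n = 4; exact permutation p = 2/16 and adjusted p = 0.688 for both classes). Melanocyte-like (1.15% ± 1.29 against 1.59% ± 1.29) and appendage-like cells (0.120% ± 0.101 against 0.354% ± 0.270) took a lower share at the scalp than at the vehicle site in 4 of 4 donors (exact permutation p = 2/16 and adjusted p = 0.688 for both). Some of these agreements over donors rest on few cells. In replicate 3 there were 5 lymphatic endothelial-like cells at the sole and 3 at the vehicle site. There were also 16 melanocyte-like cells at its scalp and 17 at its vehicle site. In replicate 4 there was 1 appendage-like cell at the scalp site against 6 at the vehicle site. The design allows no p below 2/16, so no share could pass the threshold. Fibroblast-like cells were 3.28 points higher at the sole than at the scalp site on average, which became -2.33 points without replicate 1.

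The clusters behind a class followed the donor. Among fibroblast-like cells, cluster 11 held 31.1%, 69.2% and 43.0% of the vehicle, scalp and sole cells of replicate 1 and at most 4.2% in the other replicates, where clusters 12 and 16 held most cells of replicates 2 and 4. Cluster 3, with low UMI counts, held 31.4% of the fibroblast-like cells of the sole site of replicate 1, 18.5% at its vehicle site and 3.3% at its scalp site. Among keratinocyte-like cells, clusters 27 and 29 held 86.8% to 91.6% of those of replicate 3.

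**Figure D2:**
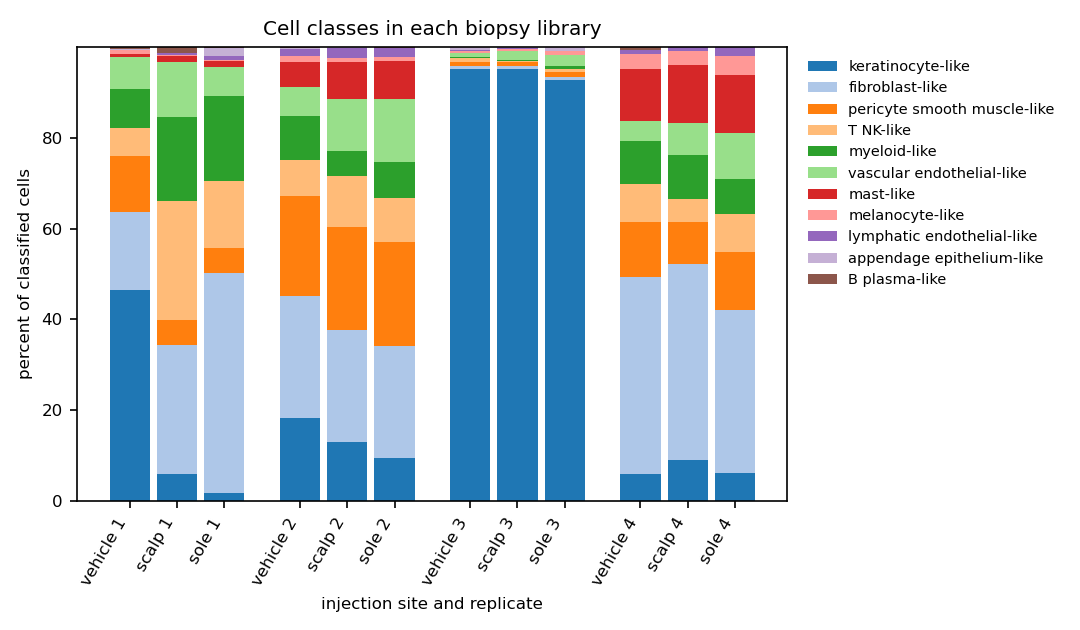
Percent of classified cells (vertical axis) in each of 11 cell classes (colours), as 1 stacked bar per biopsy library, grouped by replicate in the order vehicle, scalp and sole site. No mean or error bar is drawn. Keratinocyte-like cells lie at 92.7% to 95.3% in replicate 3 and at 1.70% to 46.5% in the other donors.

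Sole against scalp sites is the comparison of volar with other injected fibroblasts, and the first class is the overlying keratinocyte-like cells. At sole sites basal cells and basal transcripts leaned lower in this class, with no gene past the threshold. The 2 basal clusters made up 26.1% ± 15.7 of the keratinocyte-like cells at sole and 35.1% ± 11.8 at scalp sites, lower at sole sites in 4 of 4 donors (SD, n = 4). This difference was not tested, and the sole value of replicate 1 was 4.17% of 96 cells. Of 16 measured basal keratinocyte genes, 15 had a negative change, with a median log2 change of -0.24 (limma camera, adjusted p = 2.82e-08; adjusted p = 0.549 with an estimated correlation). In suprabasal cells alone 12 of the 16 were negative, with a median of -0.03 (adjusted p = 0.103; adjusted p = 0.815 with an estimated correlation). The change over the whole class may therefore include a change in its mix of cells, and its size was not tested. COL17A1, the hemidesmosome collagen, was at 348 ± 150 CPM at sole and 446 ± 159 at scalp sites (log2 change -0.39, SE 0.09, lower in 4 of 4 donors). TP63, the master regulator of stratified epithelia, was at -0.30 (SE 0.08, 4 of 4) and KRT14 at -0.25 (SE 0.09, 3 of 4). The genes with the smallest p were also lower at sole sites in 4 of 4 donors: TGFBI (74.2 ± 29.9 against 103 ± 32.3 CPM, log2 change -0.47, SE 0.08), the matricellular gene POSTN (285 ± 153 against 404 ± 179 CPM, -0.53, SE 0.10), LAMB4 (-0.41), the collagen receptor gene ITGA2 (-0.38) and IGFBP5 (-0.47). Sweat gland genes had positive changes in 13 of 14 members (median log2 change 0.73, adjusted p = 5.47e-06; adjusted p = 0.240 with an estimated correlation), with DCD at 1.78 (SE 0.60, higher in 3 of 4 donors) and KRT7 at 1.88 (SE 0.78, 4 of 4). Appendage-like cells, a class of their own with DCD and KRT7 among the top genes of their cluster, were 0.633% ± 0.802 of cells at sole and 0.120% ± 0.101 at scalp sites, higher at sole sites in 2 of 4 donors. At the sole site of replicate 1 there were 97 of them beside 96 keratinocyte-like cells, so a change within keratinocytes was not shown. Proliferation genes had positive changes in 23 of 27 members (median 0.19, adjusted p = 0.00242; adjusted p = 0.549 with an estimated correlation), with STMN1 at 0.56 and TOP2A at 0.46, but cluster 19, which held the cycling cells, was unnamed and left out here. Alarmins (8 of 10, adjusted p = 0.0150) and immune transcripts (16 of 18, adjusted p = 0.00228) were positive as well, both with adjusted p = 0.549 with an estimated correlation.

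KRT9 (ENSG00000171403), the keratin of palm and sole epidermis, passed the threshold in no comparison of sites. It was at 3.53 ± 3.64 CPM at sole, 4.57 ± 2.83 at scalp and 3.28 ± 0.699 at vehicle sites (SD, n = 4). The log2 changes were -0.75 (SE 0.38) for sole against scalp, -0.42 (SE 0.38) for sole against vehicle and 0.34 (SE 0.34) for scalp against vehicle (edgeR adjusted p = 0.977, 0.8294 and 0.926). The mean was higher at sole than at vehicle sites while the fitted change was negative, because 1 donor (replicate 1, 8.98 CPM at the sole site, 96 cells) carried the mean and 3 of 4 donors were lower. The suprabasal keratins KRT1 (5962 ± 3005 against 5311 ± 2469 CPM) and KRT10 had log2 changes of 0.13 and 0.07 between sole and scalp sites. KRT6A, KRT16 and KRT17, keratins of palms, soles and wounds, had fitted log2 changes of 0.67, 0.47 and 0.86, each within 2 SE. Their means showed no common direction: KRT6A was at 117 ± 79.8 CPM at sole and 119 ± 128 at scalp sites (higher at sole sites in 2 of 4 donors), KRT16 at 209.8 ± 189 and 211 ± 272 (1 of 4) and KRT17 at 575 ± 309 and 399 ± 394 (3 of 4). The list of volar and stress keratins gave an adjusted p of 0.269 (median 0.57, 5 of 6 positive). KRT15, a basal keratin, was at 850 ± 370 CPM at sole, 1148 ± 153 at scalp and 1198 ± 177 at vehicle sites.

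No gene passed the threshold between sole and scalp sites in keratinocyte-like cells (edgeR; 759 genes at an unadjusted p under 0.05; 3 genes by DESeq2). These 759 are 4.85% of the genes tested, where about 5% would arise with no difference at all, so the genes named above as not passing carry little weight singly. Camera called 5 of 35 lists, 4 up and 1 down, and 0 with an estimated correlation. The number of lists was 11 without replicate 1, 10 without replicate 2 and 11 without replicate 4. Without replicate 3 it was 5, of which 2 were among the 5 called with all replicates.

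**Figure D3:**
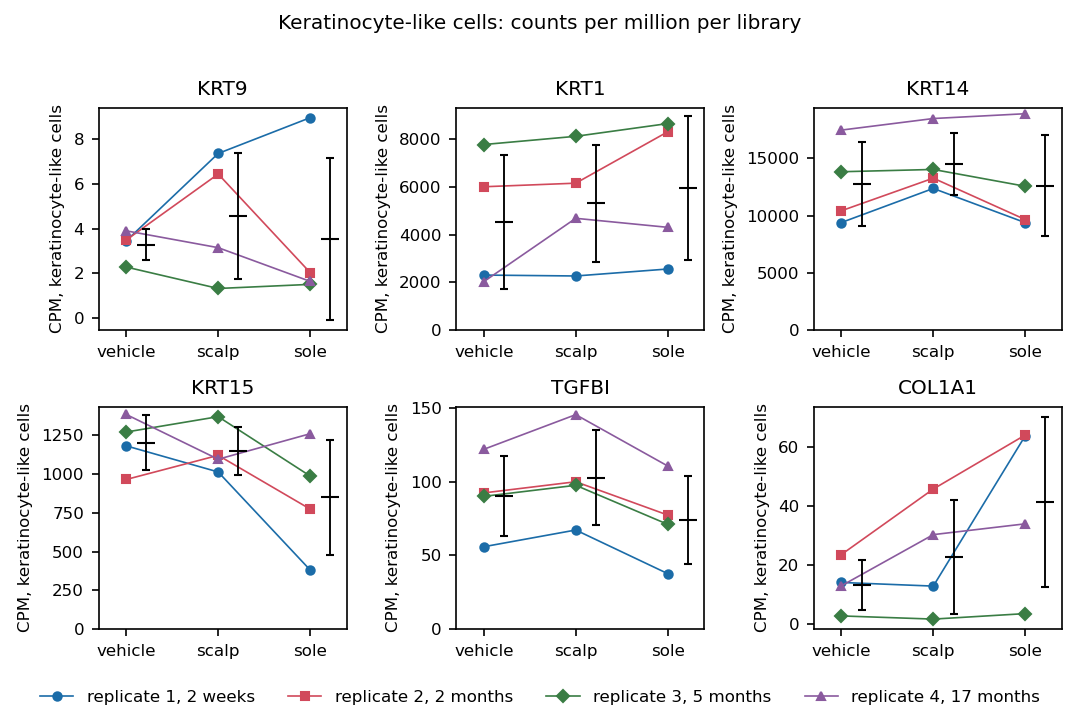
CPM (vertical axes) of KRT9, KRT1, KRT14, KRT15, TGFBI and COL1A1 in keratinocyte-like cells at vehicle, scalp and sole sites, with 1 point per donor, lines joining the sites of a donor, and the mean with SD over 4 donors. TGFBI averages 74.2 CPM at sole and 103 CPM at scalp sites, while KRT9 lies between 1.31 and 8.98 CPM at all sites.

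Against vehicle sites, keratinocyte-like cells of sole sites had fewer transcripts of a hair gene, and transcripts typical of the dermis leaned higher without passing. The hair-associated gene PRR9 (ENSG00000203783), named after its value was seen, fell (2.32 ± 4.44 against 12.7 ± 23.2 CPM, log2 change -2.83, SE 0.29, lower in 4 of 4 donors, edgeR adjusted p = 0.00412). The collagen genes COL1A1 (41.3 ± 28.8 against 13.4 ± 8.49 CPM, log2 change 1.34, SE 0.28), COL1A2 (1.08, SE 0.19) and COL3A1 (1.27, SE 0.27) were higher in 4 of 4 donors without passing. Of 18 fibroblast transcripts, 16 had positive changes (median 0.19, camera adjusted p = 0.000248; adjusted p = 0.484 with an estimated correlation). Immune transcripts (16 of 18 positive, median 0.38, adjusted p = 1.84e-05) and vascular transcripts (9 of 11, median 0.64, adjusted p = 0.00360) moved the same way, both with adjusted p = 0.389 with an estimated correlation. The mast cell gene TPSB2 was at 2.39 (SE 0.47). Immediate early genes, which respond within minutes to stimuli and to dissociation, had negative changes in 27 of 31 members (median -0.28, adjusted p = 3.61e-08; adjusted p = 0.389 with an estimated correlation), including JUN (-0.28), EGR2 (-0.75) and NR4A1 (-0.52). BMP and FGF signalling genes were negative in 19 of 25 (median -0.28, adjusted p = 0.00218; adjusted p = 0.228 with an estimated correlation). Of these, 4 passed the threshold adjusted over the list alone and 0 over all genes, and the list included the pathway inhibitor SMAD7 (-0.51) and the BMP target ID1 (-0.41). Interferon response genes were positive in 18 of 24 (median 0.14, adjusted p = 0.00829; adjusted p = 0.608 with an estimated correlation), with ISG15 at 0.71. Basal keratinocyte genes were negative in 15 of 16 (median -0.15, adjusted p = 0.00322; adjusted p = 0.664 with an estimated correlation), with BCAM at -0.46 and KRT15 at -0.56. KRT1 and KRT10 were at 0.44 (SE 0.16) and 0.32 (SE 0.13), higher in 4 of 4 donors.

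In this comparison 1 gene passed (1199 at an unadjusted p under 0.05; 7 by DESeq2, PRR9 not among them). Without replicate 1, whose vehicle site had 47.5 CPM of PRR9 against at most 2.498 at the others, 1 gene passed and PRR9 had too few counts to be tested. The count was 0 without replicate 3, 3 without replicate 2, 2 without replicate 4 and 0 without the keratinocyte clusters given to no stratum. Camera called 13 lists, 7 up and 6 down, and 0 with an estimated correlation.

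Keratinocyte-like cells of scalp sites had fewer hair keratin transcripts than those of vehicle sites. The hair keratin genes KRT85 (ENSG00000135443; 1.85 ± 3.68 against 83.3 ± 149 CPM, log2 change -6.30, SE 0.76, edgeR adjusted p = 0.0115) and KRT35 (ENSG00000197079; 1.86 ± 3.67 against 54.8 ± 105 CPM, -5.22, SE 0.60, adjusted p = 0.0134) fell, as did PRR9 (-4.43, SE 0.31, adjusted p = 4.02e-05). KRT35 and PRR9 were named after their values were seen. Most of these transcripts lay in the vehicle site of replicate 1, with 307 CPM of KRT85, 212 of KRT35 and 47.5 of PRR9. Hair follicle genes were negative in 13 of 18 members (median -0.74, camera adjusted p = 0.000465; adjusted p = 0.300 with an estimated correlation), with LHX2 at 0.922 against 6.15 CPM and SOSTDC1 at a log2 change of -0.73. Sweat gland genes were negative in 14 of 14 (median -0.65, adjusted p = 4.82e-09; adjusted p = 0.0931 with an estimated correlation), with KRT8 at -1.07 (SE 0.28). Appendage-like cells were also fewer at scalp sites (0.120% against 0.354%, 4 of 4 donors). Immediate early genes (28 of 31, median -0.26, adjusted p = 1.69e-08; adjusted p = 0.0931 with an estimated correlation) and TNF and IL1 response genes (20 of 24, median -0.26, adjusted p = 2.79e-05; adjusted p = 0.123 with an estimated correlation) were negative as well, with DUSP2 at -0.81, GADD45B at -0.36, TNFAIP3 at -0.67 and CXCL3 at -0.80. Fibroblast transcripts were positive in 16 of 18 (median 0.34, adjusted p = 1.02e-05; adjusted p = 0.318 with an estimated correlation), with DCN at 0.33 and COL3A1 at 0.81. Without passing, G0S2 (-1.24, SE 0.20) and the fatty acid binding gene FABP7 (-1.58, SE 0.38) were lower, and TPPP3 (0.70, SE 0.11) and the imprinted RNA H19 (0.87, SE 0.19) higher, in 4 of 4 donors.

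In this comparison 3 genes passed, all lower at scalp sites (980 at an unadjusted p under 0.05; 6 by DESeq2). The count was 1 without replicate 1, 9 without replicate 2, 7 without replicate 4 and 0 without the keratinocyte clusters given to no stratum. Camera called 16 lists, 6 up and 10 down, and 0 with an estimated correlation.

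As a test of volar identity cell by cell, KRT9 was counted in suprabasal keratinocyte-like cells thinned to 2000 UMIs. The share of cells with a KRT9 UMI was 0.0763% ± 0.153 at sole, 1.33% ± 2.00 at scalp and 0.383% ± 0.445 at vehicle sites (SD, n = 4). The differences of -1.26, -0.306 and 0.949 points for sole minus scalp, sole minus vehicle and scalp minus vehicle each had an exact permutation p of 0.5. The thinned data hold 9462 cells, and 299 cells under 2000 UMIs were left out. At sole sites the share was 0 of 51 cells in replicate 1, which allows up to 5.88%, 0 of 527 in replicate 2 (up to 0.569%), 6 of 1966 in replicate 3 (0.305%, exact interval 0.112% to 0.663%) and 0 of 287 in replicate 4 (up to 1.05%). The highest share, 4.26% (4 of 94 cells, 1.17% to 10.5%), was at the scalp site of replicate 1, and without that replicate the sole minus scalp difference was -0.255 points. With all replicates it was -0.0184 points thinned to 1000 UMIs and 0.346 with predicted doublets kept. As background, 0 of 5193 vascular endothelial-like cells and at most 0.221% of fibroblast-like cells per library had a KRT9 UMI, so the mean at sole sites lay within the background range. Median depths before thinning were 8604.5 to 20436 UMIs per suprabasal and 4208 to 13034 per endothelial-like cell. Unthinned, the shares were 3.07%, 4.11% and 3.01% at sole, scalp and vehicle sites, with up to 2.47% in fibroblast-like cells.

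In fibroblast-like cells, which would include any injected cells that remained, the lists with the smallest p between sole and scalp sites were proliferation, ribosomal protein and immune genes, and single matrix genes leaned higher at sole sites. Without passing the threshold, COMP, a matrix glycoprotein, was at 134 ± 111 CPM at sole and 47.8 ± 52.8 at scalp sites (log2 change 1.84, SE 0.32). It was the top gene of cluster 6, which held more of the fibroblast-like cells at sole than at scalp sites in 3 of 3 donors (1.02% against 0.319%, 9.79% against 6.22% and 12.9% against 2.94%). COMP, DIRAS3 (1.80, SE 0.32), the basement membrane collagen gene COL18A1 (0.87, SE 0.22) and TGFBI (0.65, SE 0.13) were higher in 3 of 3 donors. HOXA13 was at 11.05 ± 6.63 CPM at sole, 4.66 ± 0.734 at scalp and 5.95 ± 0.428 at vehicle sites (SD, n = 3). Its log2 change between sole and scalp sites was 1.15 (SE 0.30, 3 of 3 donors, edgeR adjusted p above 0.99). HOXA11 and HOXA10 were at 0.37 and 0.26, and the 11 measured distal HOX genes gave an adjusted p of 0.265 (6 positive). Proliferation genes were negative in 25 of 26 members (median -0.34, camera adjusted p = 1.91e-12; adjusted p = 0.169 with an estimated correlation), with RRM2 at -1.48 and MCM5 at -0.32, again without the cycling cells of cluster 19. Ribosomal protein genes were negative in 38 of 38 (median -0.10, adjusted p = 5.50e-07; adjusted p = 0.780 with an estimated correlation). Collagens were positive in 22 of 30 (median 0.09, adjusted p = 0.0220; adjusted p = 0.780 with an estimated correlation), with COL14A1 at 0.49. Markers of other cells moved too: immune transcripts were positive in 23 of 25 (median 0.45, adjusted p = 9.18e-05), vascular transcripts in 11 of 16 (adjusted p = 0.0355), with SELE at 1.07, and haemoglobin in 3 of 3 (median 2.58, adjusted p = 0.00122). With an estimated correlation the adjusted p was 0.780, 0.440 and 0.328.

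The 100 genes most characteristic of native sole fibroblasts were, as a list at the preset correlation, higher at sole than at scalp sites (75 of 100 positive, median log2 change 0.15, camera adjusted p = 2.61e-06; adjusted p = 0.128 with an estimated correlation). By fry, which asks whether the genes of the list move on balance, p was 0.0915 for 1 direction and 0.444 for either. The 100 genes most characteristic of native scalp fibroblasts had 53 negative and 45 positive changes (median -0.03, adjusted p = 0.370). Against vehicle sites this scalp list was higher at scalp sites (62 of 98 positive, median 0.08, camera adjusted p = 0.00942, not tested with an estimated correlation). At an unadjusted p under 0.05, 15 of its members were higher and 7 lower there. It leaned the same way at sole sites (62 of 98 positive, median 0.05, camera adjusted p = 0.0625). By fry, p for the scalp list was 0.390 at scalp and 0.420 at sole sites. Against vehicle sites the sole list was not higher at sole sites (50 of 100 positive, median 0.00203, camera adjusted p = 0.0630). It was lower at scalp sites (60 of 100 negative, median -0.08, camera adjusted p = 0.0351, a call not tested with an estimated correlation). At an unadjusted p under 0.05, 12 members were higher and 0 lower at sole than at vehicle sites, and 2 were higher and 11 lower at scalp than at vehicle sites. By fry, p was 0.470 for sole against vehicle and 0.249 for scalp against vehicle. No member of either list passed the threshold over all genes between sole and scalp sites, and adjusted over the list alone the counts were 0 and 1. After thinning to 2000 UMIs, 2.19% ± 1.75 of fibroblast-like cells at sole, 1.21% ± 0.302 at scalp and 1.59% ± 0.468 at vehicle sites had a HOXA13 UMI (SD, n = 3), against at most 0.376% of vascular endothelial-like cells per library. Unthinned, the shares were 8.79% ± 3.50, 7.02% ± 3.77 and 7.33% ± 0.616. The thinned difference between sole and scalp sites, 0.980 points, had an exact permutation p of 0.5, with 0.25 the smallest possible for 3 donors. It was positive in 2 of 3 donors, -0.318 points in replicate 2, and 0.161 points on average without replicate 1. In replicate 1 the share was 4.16% at the sole (exact interval 3.32% to 5.16%), 1.55% at the scalp (0.847% to 2.58%) and 2.07% at the vehicle site (0.997% to 3.77%). Thinning left out 1335 fibroblast-like cells under 2000 UMIs, 828 of them at that sole site. Median depths before thinning were 9801 to 20878 UMIs per fibroblast-like cell in these 3 replicates and 8683 to 13034 per endothelial-like cell.

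No gene passed between sole and scalp sites in fibroblast-like cells (edgeR; 722 genes at an unadjusted p under 0.05; 9 by DESeq2). These 722 are 3.83% of the genes tested, no more than the 5% that no difference would give. Camera called 10 of 36 lists, 4 up and 6 down, and 0 with an estimated correlation, and the number was 3 without replicate 1.

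Against vehicle sites, collagen genes of fibroblast-like cells leaned higher at sole sites, with 0 genes past the threshold (edgeR; counts below). Collagen genes were positive in 23 of 30 members (median 0.28, camera adjusted p = 1.36e-07; adjusted p = 0.478 with an estimated correlation), with COL3A1 at 10054 ± 4688 against 5382 ± 1992 CPM (log2 change 0.83, SE 0.20, 3 of 3 donors), COL1A1 at 0.65 (SE 0.24) and COL14A1 at 0.71 (SE 0.18). The matrix gene DPT (510 ± 115 against 318 ± 37.9 CPM, 0.66, SE 0.11), the hyaluronan synthase gene HAS1 (0.59, SE 0.11) and FAP, a protease of activated fibroblasts (122 ± 42.2 against 62.8 ± 6.16 CPM, 0.90, SE 0.19), were higher in 3 of 3 donors without passing. SEMA4A (15.1 ± 3.99 against 26.6 ± 7.57 CPM, -0.81, SE 0.10), the antioxidant gene GPX3 (-1.51, SE 0.29) and tissue factor, F3 (-1.05, SE 0.20), were lower in 3 of 3. Distal HOX genes were positive in 8 of 11 (median 0.69, adjusted p = 0.00266; adjusted p = 0.478 with an estimated correlation), with 1 past the threshold adjusted over the list alone. HOXD11 was at 0.727 against 0.0816 CPM (3.12, SE 0.63), HOTTIP, a noncoding RNA of the HOXA cluster, at 1.10 against 0.209 CPM (1.95, SE 0.61) and HOXA13 at 0.73 (SE 0.30, 2 of 3 donors). Immediate early genes were negative in 28 of 31 (median -0.31, adjusted p = 2.04e-10; adjusted p = 0.458 with an estimated correlation), with EGR1 at -0.61 and EGR3 at -0.77. Proliferation genes, without the cycling cells of cluster 19, were negative in 23 of 26 (median -0.22, adjusted p = 4.16e-06; adjusted p = 0.458 with an estimated correlation). Immune (22 of 25, median 0.89, adjusted p = 1.37e-09) and vascular transcripts (14 of 16, median 0.29, adjusted p = 1.92e-05) were positive, with LYZ at 1.28 and PECAM1 at 1.28. With an estimated correlation the adjusted p was 0.478 and 0.263.

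In this comparison 0 genes passed (edgeR; 1501 at an unadjusted p under 0.05; 27 by DESeq2). Camera called 12 lists, 5 up and 7 down, and 0 with an estimated correlation, and the number was 19 without replicate 4.

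In fibroblast-like cells of scalp sites Wnt and hair-papilla genes leaned lower than at vehicle sites, with no member past the threshold. Wnt inhibitors were negative in 13 of 15 members (median -0.45, camera adjusted p = 0.0420; adjusted p = 0.567 with an estimated correlation), with WIF1 at 12.98 ± 9.08 against 25.5 ± 9.45 CPM (log2 change -1.30, SE 0.49), APCDD1 at -1.27 (SE 0.30) and SFRP1 at -0.79. WIF1 and APCDD1 were top genes of cluster 6, which held fewer of the fibroblast-like cells at scalp than at vehicle sites in 3 of 3 donors (0.319% against 3.95%, 6.22% against 8.60% and 2.94% against 9.09%). Lower levels may therefore reflect fewer such cells. Wnt targets and agonists were negative in 18 of 26 (median -0.33, adjusted p = 0.0192; adjusted p = 0.567 with an estimated correlation), with RSPO1 at -1.39 (SE 0.23). Dermal papilla genes were negative in 19 of 27 (median -0.19, adjusted p = 0.00623; adjusted p = 0.567 with an estimated correlation), with 7 past the threshold adjusted over the list alone and 0 over all genes. The protease gene CORIN (3.70 ± 2.32 against 11.9 ± 8.92 CPM, -1.63, SE 0.25) and the hedgehog inhibitor gene HHIP (-1.28, SE 0.31) were lower in 3 of 3 donors. BMP and FGF signalling genes were negative in 24 of 32 (median -0.14, adjusted p = 0.00213; adjusted p = 0.470 with an estimated correlation), with SPRY4 at -0.79. Collagens (24 of 30 positive, median 0.21, adjusted p = 0.00195) and immune transcripts (23 of 25 positive, median 0.47, adjusted p = 0.00116) were positive and immediate early genes negative (24 of 31, median -0.20, adjusted p = 0.000128), with DUSP1 at -0.39 and FOS at -0.45. With an estimated correlation the adjusted p was 0.567, 0.580 and 0.470. The carbonic anhydrase gene CA3 (ENSG00000164879), named after its value was seen, rose (12.6 ± 21.1 against 3.31 ± 5.58 CPM, 1.96, SE 0.17, higher in 3 of 3 donors, edgeR adjusted p = 0.0309), with most counts in replicate 1, at 37.0 against 9.76 CPM.

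In this comparison 1 gene passed (1356 at an unadjusted p under 0.05; 29 by DESeq2), and 0 passed without replicate 1, 2 or 4 or at a mitochondrial share of at most 10%. Camera called 10 lists, 4 up and 6 down, and 0 with an estimated correlation, and the number was 17 without replicate 2.

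**Figure D4:**
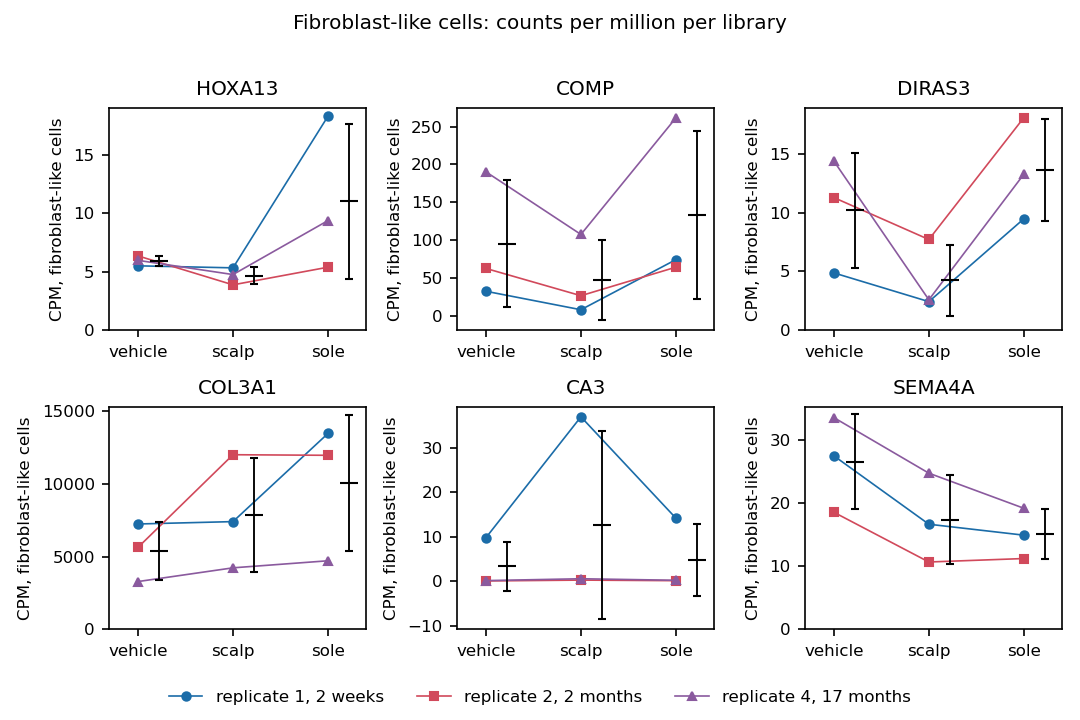
CPM (vertical axes) of HOXA13, COMP, DIRAS3, COL3A1, CA3 and SEMA4A in fibroblast-like cells at vehicle, scalp and sole sites of replicates 1, 2 and 4, with 1 point per donor, lines joining the sites of a donor, and the mean with SD over 3 donors. COMP averages 134 CPM at sole and 47.8 CPM at scalp sites, and HOXA13 averages 11.05 and 4.66 CPM.

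The vessels carried most of the genes past the threshold, and the genes named for these classes were chosen after their values were seen. In vascular endothelial-like cells, the basement membrane collagen gene COL4A1 rose at sole (248 ± 184 CPM, log2 change 0.67, SE 0.11) and at scalp sites (280 ± 254 CPM, 0.73, SE 0.11) against vehicle sites (159 ± 121 CPM), in 4 of 4 donors each (edgeR adjusted p = 0.0212 and 0.00514). PRND, a prion-like protein gene of growing vessels, rose too (4.51 ± 1.66 at sole and 6.60 ± 6.39 at scalp sites against 0.232 ± 0.465 CPM). The immediate early genes ZFP36 (-0.47 and -0.57) and BTG2 (-0.59 and -0.66) fell at both, and DUSP1 (-0.64), NR4A1 (-0.72), FOS (-0.60) and the chemokine gene CX3CL1 (-0.98) fell at scalp sites. The endothelial-like cells also lay in different clusters by site. Cluster 23, with SELE and IL6 among its top genes, held fewer of them at scalp than at vehicle sites in replicates 2, 3 and 4 (41.3% against 54.1%, 63.6% against 73.5% and 20.3% against 40.4%) and slightly more in replicate 1. Cluster 20 held more in 4 of 4 donors, and changes within a cluster were not tested in this class. Between sole and scalp sites the contractile gene TPM2 (16.2 ± 9.19 against 7.36 ± 4.99 CPM, 1.07, SE 0.15, 4 of 4 donors) and the chemokine genes CCL19 (4.27, SE 0.53) and CCL21 (2.11, SE 0.33) rose. These are also marks of other cells here, since TPM2 was a top gene of a pericyte-like, CCL21 of a lymphatic and, at other clustering resolutions, CCL19 of a fibroblast-like cluster. Transcripts or cells of those types among the endothelial-like cells were not tested. The counts were 4 genes for sole against scalp (all higher), 8 for sole against vehicle (5 higher) and 41 for scalp against vehicle (14 higher), with 1, 8 and 56 by DESeq2. They were 0, 1 and 0 without replicate 3, and for scalp against vehicle 21 without replicate 2, 70 without replicate 1 and 118 without replicate 4. For sole against vehicle they were 13 without replicate 1 and 60 without replicate 4, and for sole against scalp 1 without replicate 1. Replicate 3, on which most of these calls depended, held only 34, 66 and 93 such cells at its vehicle, scalp and sole sites.

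The pericyte-like class may also hold smooth muscle cells, whose markers were used to name it. In pericyte-like cells the matrix gene POSTN rose at sole (142 ± 220 CPM, 1.15, SE 0.20) and scalp sites (158 ± 233 CPM, 1.43, SE 0.20) against vehicle sites (47.2 ± 63.3 CPM), in 4 of 4 donors each (edgeR adjusted p = 0.0388 and 0.00599). The protease gene PRSS23 (1.14 and 1.07) and the smooth muscle noncoding RNA CARMN (0.82 and 0.90) rose as well. At scalp sites COL4A2 (0.67), FBN1 (0.58) and LAMB1 (0.88) also rose. POSTN and FBN1 were among the markers used to name fibroblast-like cells. Transcripts or cells of that class among the pericyte-like cells were not tested. The inflammatory regulators ZFP36 (-1.07, at sole sites) and NFKBIA (-0.81 at sole, -0.59 at scalp sites), the transcription factor JUNB (2651 ± 1156 against 4684 ± 1466 CPM, -0.96) and the metabolic kinase gene PDK4 (74.0 ± 53.1 against 283 ± 197 CPM, -1.65) fell, the last pair at scalp sites. Immediate early genes were negative in 31 of 31 members at both sites, with a median of -0.77 (camera adjusted p = 3.94e-18 at sole and 9.28e-17 at scalp sites; adjusted p = 0.275 and 0.317 with an estimated correlation). The counts were 0 genes for sole against scalp (edgeR; 217 at an unadjusted p under 0.05; 0 by DESeq2), 10 for sole against vehicle (5 higher; 16 by DESeq2) and 91 for scalp against vehicle (29 higher; 99 by DESeq2). For scalp against vehicle they were 13 without replicate 1, 37 without replicate 2, 0 without replicate 3 and 597 without replicate 4, and for sole against vehicle 0, 20, 0 and 378. Replicate 3, without which both counts were 0, held only 35, 37 and 36 pericyte-like cells at its vehicle, scalp and sole sites. Whether the sole and scalp responses differ was tested only by the direct comparison of sole with scalp sites.

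In suprabasal keratinocyte-like cells 0 genes passed in each comparison (edgeR; 578, 1043 and 653 at an unadjusted p under 0.05 for sole against scalp, sole against vehicle and scalp against vehicle; 0, 7 and 2 by DESeq2). Immediate early genes were again negative against vehicle sites, in 29 of 31 members at sole (median -0.43) and 30 of 31 at scalp sites (median -0.32; camera adjusted p = 2.12e-15 and 2.82e-15; adjusted p = 0.241 and 0.0568 with an estimated correlation). Across 8 cell classes that share no cells the median of these genes was negative in 7 for sole against vehicle, in 8 for scalp against vehicle and in 5 for sole against scalp. These classes came from the same biopsies and donors, so the 8 are not independent. Sites with fewer than 20 cells of a class were left out. The sole site of replicate 1 was therefore absent for melanocyte-like (11 cells) and basal keratinocyte-like cells (4.17% of 96). Its scalp site was kept for basal cells (20% of 195), so their 2 comparisons with vehicle sites cover unlike donors. Only replicates 2 and 4 had all 3 sites for melanocyte-like cells. The exception against vehicle was melanocyte-like cells, with a median of 0.34 at sole sites (23 of 30 positive, camera adjusted p = 7.84e-11; adjusted p = 0.405 with an estimated correlation). In basal keratinocyte-like cells, tested apart, no fall was seen at sole sites (16 of 31 positive, median 0.00, camera adjusted p = 0.694; adjusted p = 0.887 with an estimated correlation), while 26 of 31 members were negative at scalp sites (median -0.25, camera adjusted p = 1.11e-14; adjusted p = 0.143 with an estimated correlation).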

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

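Chosen after the result was seen were the tests that remove cells rich in collagen or clusters with few UMIs, and the counts of other splits of the samples except those for pericyte-like cells and for the native sole list; the other tests were written before.

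In 16 of 87 groups of 4 biopsies 1 value lay far from the other 3, where chance gives about 1 in 20 groups (4.35 of 87). The 16 are not independent and cannot be set against that number: 9 are PRR9, KRT85 and KRT35 at the 3 sites of replicate 1, which move together, and PRR9 and KRT35 were named after their values were seen. Of the 16, 12 belonged to replicate 1 and 4 to replicate 3. Hair genes stood out at every site of replicate 1: PRR9 at 47.5 CPM at the vehicle (others 0.163 to 2.498), 2.46 at the scalp (0 to 0.0741) and 8.98 at the sole site (0 to 0.214); KRT85 at 307 (1.32 to 20.7), 7.37 (0 to 0.0424) and 88.0 CPM (others 0); KRT35 at 212 (0 to 7.27), 7.37 (0 to 0.0847) and 55.7 CPM (others 0). At the sole site of replicate 1, which held 96 keratinocyte-like cells, KRT9 was at 8.98 CPM (1.497 to 2.03) and MKI67 at 14.4 CPM (2.11 to 2.48). B and plasma-like cells were 1.30% of the scalp site of replicate 1 (others 0% to 0.0952%). In replicate 3, keratinocyte-like cells were 95.3% of the scalp (5.90% to 12.97%) and 92.7% of the sole site (1.70% to 9.41%), and myeloid-like cells 0.204% of the vehicle site (8.59% to 9.66%). The share of suprabasal cells with KRT9 at its sole site was 0.305% (others 0%), but the others are 0 of 51, 527 and 287 cells, with upper limits of 5.88%, 0.569% and 1.05%, so this value is not shown to differ. Replicates 1 and 3 differ from the others in donor and in time after injection, and no explanation was tested.

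As a list at the preset correlation, fibroblast transcripts were higher in keratinocyte-like cells of sole than of vehicle sites. The call was lost with an estimated correlation, and no fibroblast transcript passed the threshold over all genes. Free RNA from fibroblasts could give the higher levels: over 18 genes the change in keratinocyte-like cells minus that over all cells had a median of -0.0803 (SD 0.267), so these cells followed the whole suspension. Doublets of both cell types could not be told apart from it, since cells with at least 20 collagen UMIs held 18.7% of the collagen UMIs of injected sites, 30.1% in 9 cells at sole and 6.58% in 4 cells at scalp sites. Without such cells the collagen change was 0.840 (SD 0.894) against 1.20 (SD 0.789), higher in 4 of 4 donors. A response of the keratinocytes to sole fibroblasts stays open as untested.

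Genes of native sole fibroblasts were higher in fibroblast-like cells of sole than of scalp sites. Clusters with few UMIs are argued against, since the adjusted p without them was 3.84e-06 (limma camera; 1.48e-09 to 0.128 over the alternatives). Against vehicle sites the list was not higher at sole sites (50 of 100 positive, adjusted p = 0.0630; 12 members higher and 0 lower at an unadjusted p under 0.05) and lower at scalp sites (adjusted p = 0.0351; 2 higher and 11 lower). By fry, which asks whether the genes of the list move on balance, p was 0.470 for the first and 0.249 for the second. Injected sole cells that remained could contribute, and this stays open. The log2 ratio of the list between cells with and without HOXA13 was larger at the sole than at the scalp site in 2 of 3 donors. The differences were 0.018, -0.190 and 0.041. At vehicle sites, which received no cells, the ratio was -0.050, 0.171 and 0.079, against 0.061, 0.148 and 0.017 at sole sites. Fibroblast-like cells of vehicle sites also held HOXA13 (5.95 CPM on average). HOXA13 therefore cannot mark injected cells, and the ratio cannot decide. Of the 10 splits of the 6 samples 3 gave as small a p, the real split included. The real -log10 p was 5.89, and the highest other was 6.77. Among the 4 splits that part every donor's pair 2 gave as small a p, the real split included. The highest other of these 4 was also 6.77. Both numbers of splits are too few for a share under 0.05.

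Between scalp and vehicle sites 91 genes passed in pericyte-like cells. With the immediate early level of the keratinocyte-like cells as a covariate 85.2% of the median size was left (76.1% to 94.0%), from 1.03 (MAD 0.300) to 0.877 (MAD 0.331). The calls went from 91 to 4 with residual degrees of freedom from 6 to 5. The size left met the bound set beforehand against a dissociation response shared by all classes as the whole cause. The test cannot exclude that response. The covariate came from another class, where the median immediate early change was -0.26 against -0.77 in pericyte-like cells. The bounds given in this paragraph resample genes and not donors. A shift between the 2 clusters of the pericyte-like class, named from pericyte and smooth muscle markers together, could not be excluded. The size left was 63.8% within cluster 5 (54.1% to 70.8%) and 87.4% within cluster 17 (79.8% to 96.8%). A response to the injected fibroblasts stays open as untested.

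The numbers below count the splits of the same samples that gave as many results, with the real split included. A count of 1 therefore means that only the real split did. Where the real number is 0 every split gives as many by construction, so the count decides nothing; in the other comparisons chance could not be excluded. In keratinocyte-like cells, for sole against scalp, sole against vehicle and scalp against vehicle, 35, 16 and 4 of the 35 splits gave as many genes (real 0, 1 and 3; highest other 11, 6 and 5) and 32, 7 and 4 as many lists (real 5, 13 and 16; highest other 18, 17 and 20). In suprabasal cells 35 of the 35 splits did in each (real 0; highest other 2, 24 and 1), in vascular endothelial-like cells 10, 6 and 2 (real 4, 8 and 41; highest other 72, 32 and 70), and in pericyte-like cells 35, 6 and 4 (real 0, 10 and 91; highest other 201, 846 and 1071). Splits that call several times the real number point to a structure of the samples: among the 8 splits that part every donor's pair the highest other counts were 4, 4 and 31 genes in vascular and 1, 14 and 86 in pericyte-like cells. Of these 8, the real split included, 2, 1 and 1 gave as many genes in vascular and 8, 2 and 1 in pericyte-like cells. A total of 8 splits is too few for a share under 0.05. The other splits put both sites of a donor on 1 side. In fibroblast-like cells the 10 splits are too few for a share under 0.05: 10, 10 and 1 gave as many genes (real 0, 0 and 1; highest other 2, 67 and 0) and 8, 6 and 10 as many lists (real 10, 12 and 10; highest other 18, 17 and 17).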

How the results depend on the processing

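Added after seeing the data were the alternatives without clusters with few UMIs, without keratinocyte clusters of no stratum, with at least 100 cells per library, without HOX and proliferation genes, and, in vascular, pericyte and suprabasal classes, leaving out a replicate and DESeq2. The cause was not tested for any change below.

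Counts are given for sole against scalp, sole against vehicle and scalp against vehicle. Genes past the threshold in keratinocyte-like cells were 0, 1 and 3 (edgeR; 759, 1199 and 980 at an unadjusted p under 0.05). They were 3, 7 and 6 with DESeq2, 105, 254 and 341 with no filter on low counts, and 3, 7 and 5 with sums thinned to the lowest total. With no replicate block they were 0, 0 and 0, and without keratinocyte clusters of no stratum 0, 0 and 0. For sole against vehicle they were 3 with at least 1000 UMIs per cell and 3 with at least 100 cells. Leaving out a replicate gave 0 to 0, 0 to 3 and 1 to 9. In fibroblast-like cells the counts were 0, 0 and 1, with DESeq2 9, 27 and 29, with no filter on low counts 13, 12 and 24, with thinned sums 0, 3 and 4, with only the 2 groups compared 1, 0 and 0, and with no replicate block 0, 0 and 0. For scalp against vehicle the count was 0 at a mitochondrial share of at most 10%. Leaving out a replicate gave 0 to 0, 0 to 0 and 0 to 1. Lists numbered 5, 13 and 16 in keratinocyte-like and 10, 12 and 10 in fibroblast-like cells, and 0 in all 6 with an estimated correlation. With no replicate block they numbered 7, 8 and 14, and 4, 11 and 8. For keratinocyte-like cells of sole against scalp sites they were 8 with predicted doublets kept and 8 with at least 100 cells. Leaving out a replicate gave 5 to 11, 10 to 15 and 11 to 21 lists in keratinocyte-like and 3 to 15, 10 to 19 and 9 to 17 in fibroblast-like cells.

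In suprabasal cells DESeq2 gave 0, 7 and 2 genes and leaving out a replicate 0 to 1, 0 to 2 and 0 to 0. In vascular cells DESeq2 gave 1, 8 and 56 and leaving out a replicate 0 to 4, 1 to 60 and 0 to 118. In pericyte-like cells DESeq2 gave 0, 16 and 99 and leaving out a replicate 0 to 1, 0 to 378 and 0 to 597. With no replicate block all 9 counts were 0. The native sole list had an adjusted p of 0.128 with an estimated correlation and 1.48e-09 to 0.0168 leaving out a replicate. The native scalp list had 0.0102 at 200 CPM or more and 0.0298 to 0.378 leaving out a replicate, and was reversed without replicate 4 (adjusted p = 0.139).

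The fibroblast share was reversed without replicate 1, at -2.33, -3.11 and -0.776 points, with ranges of -2.33 to 6.85, -3.11 to 9.88 and -0.776 to 3.71 leaving out a replicate. The KRT9 share was reversed with predicted doublets kept, at 0.346, 0.181 and -0.164 points. Sole minus scalp, at -1.26 points, was -0.0184 thinned to 1000 UMIs, -0.243 at Leiden resolution 0.5, -0.643 at a mitochondrial share of at most 10% and -0.255 without replicate 1. Sole minus vehicle was 0.0692 at Leiden resolution 0.5 and 0.0615 with no thinning, and scalp minus vehicle -0.0878 thinned to 1000 UMIs. A named gene below the threshold counts as reversed where its sign changed and its main log2 change exceeded its SE. For sole against scalp in keratinocyte-like cells these were CLP1 (-0.134 with thinned sums), KRT6A (-0.0229 with no replicate block) and, leaving out a replicate, KRT16 (-0.355 to 0.833) and FLG (-0.00796 to 0.712). Leaving out a replicate also reversed KRT6A for scalp against vehicle (-0.948 to 0.104). In fibroblast-like cells it reversed HOXA11 (-0.0674 to 0.532), HOXA10 (-0.00262 to 0.479) and DKK2 (-0.646 to 0.0415) for sole against vehicle, and DKK3 (-0.685 to 0.160) and COL1A1 (-0.0821 to 0.624) for scalp against vehicle. PRR9 and KRT35 gave no value without replicate 1, where they were not among the genes tested. Of the other named gene values 4664 were the same, 149 stronger, 16 weaker and 26 moved. For genes past the threshold in other classes 325 were the same and 549 weaker. Depth limits genes at a few CPM, such as KRT9, and classes with few cells, such as the fibroblast-like cells of replicate 3 (16 to 30 per site) and the keratinocyte-like cells of the sole site of replicate 1 (96).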

Other observations

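The detection of single genes in fibroblast-like cells and the tests in further cell classes were chosen after the data were seen, as were the genes named here. Means and donor counts cover the donors with at least 20 cells of the class at all 3 sites; the models also used single sites of other donors that reached 20 cells, such as the vehicle and sole sites of replicate 3 (24 and 23 T and NK-like cells), where CCL1 and IFNG had 0 counts.

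T and NK-like cells of sole sites carried more of the chemokine gene CCL1, which attracts T cells and monocytes, at 32.5 ± 33.4 CPM against 2.74 ± 4.75 at scalp and 1.69 ± 2.93 at vehicle sites (log2 change 3.95 and 4.06, SE 0.57 and 0.60, higher in 3 of 3 donors, edgeR adjusted p = 0.00238 and 0.00383). IFNG was lower than at vehicle sites (311 ± 194 against 472 ± 289 CPM, -0.63, adjusted p = 0.0499), in 3 of 3 donors. In basal keratinocyte-like cells ANXA3 was higher at sole than at vehicle sites (50.4 ± 31.0 against 21.0 ± 14.6 CPM, 1.24, SE 0.14, 3 of 3 donors, adjusted p = 0.000178). In mast-like cells the chemokine gene CCL4 was lower at sole than at vehicle sites (11.9 ± 3.57 against 50.7 ± 42.4 CPM, -2.47, SE 0.29, 3 of 3 donors, adjusted p = 6.17e-12), and CCL2 was higher at scalp than at vehicle sites (563 ± 129 against 232 ± 91.0 CPM, 1.11, SE 0.19, 3 of 3 donors, adjusted p = 7.31e-05). The vehicle site of replicate 1 held only 21 mast-like cells. Melanocyte-like cells gave 20, 10 and 6 genes for sole against scalp, sole against vehicle and scalp against vehicle, with means over 2 donors. The collagen genes COL1A1, COL1A2 and COL3A1 were among those higher at sole sites. These collagens are also fibroblast markers, and fibroblast transcripts among the melanocyte-like cells were not tested. Myeloid-like cells gave 0 in each (edgeR; 552, 974 and 665 at an unadjusted p under 0.05). For the genes of every class in this paragraph only edgeR with the donor block was run. DESeq2, leaving out a replicate, a model with no replicate block and other splits of the samples were not tried. How far these adjusted p values depend on such choices was therefore not tested. In vascular endothelial-like and pericyte-like cells, where these alternatives were run, the counts were 0 with no replicate block.

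After thinning to 2000 UMIs, the patterning gene MAB21L1 was seen in 0.571% of fibroblast-like cells at sole, 0.204% at scalp and 0.238% at vehicle sites, higher at sole sites in 3 of 3 donors (exact permutation p = 0.25, the smallest possible), and in 0 of 5193 vascular endothelial-like cells. HOTTIP was seen in 0.294%, 0.0549% and 0.0432%, and KRT19, the gene with the largest ratio between native sole and scalp cells, in 0.0345%, 0.0736% and 0.0310%. Unthinned, the shares were 2.77%, 1.62% and 0.844% for MAB21L1, 1.18%, 0.232% and 0.280% for HOTTIP, and 0.354%, 0.268% and 0.273% for KRT19. Thinning left out 1335 fibroblast-like and 307 endothelial-like cells, and median depths were 9801 to 20878 UMIs per fibroblast-like and 8683 to 13034 per endothelial-like cell in replicates 1, 2 and 4.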
